A study of Homo sapiens with 69 samples.

How the data were processed

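RNA was measured by sequencing in 69 libraries of HepG2, a human hepatoma cell line that keeps many hepatocyte functions. Per the labels' protocols, the libraries were polyA-selected, strand-specific by dUTP marking and paired-end. The labels give 7 groups: cells in 10% fetal bovine serum (FBS) for 24 h or 48 h, cells in lipoprotein-deficient serum (LPDS) with 2 µM simvastatin for 24 h or 48 h, cells in FBS with simvastatin for 24 h, and 2 addback groups. In the addback groups, 24 h of LPDS with simvastatin were followed by 24 h with LDL-cholesterol at 50 µg/ml or 25-hydroxycholesterol (25-HC) at 1 µg/ml. Each group had replicates 1 to 10, except the FBS+statin group, which had 9. The series' design text calls the replicates biological. Sample groups and replicate numbers came from the sample titles.

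The authors deposited raw counts per gene for all 69 libraries, which are whole numbers of read pairs or reads assigned to genes. Per the submitters' processing notes, STAR, Picard, featureCounts and DESeq2 were used and the genome build was hg19; their versions and the strand setting of the counting are not given in the sources used here. The authors also deposited variance-stabilized values on a log2 scale for 67 of the libraries, without 48 h FBS replicate 5 and FBS+statin replicate 5, and their notes give no reason. The count table had 60461 genes, of which 41 second copies of genes shared by the X and Y chromosomes held 0 counts and were dropped. At least 1 count was found for 35793 genes. Gene symbols came from a table of gene identifiers, which matched 55725 of them. Only a reference of another build was at hand, so no coordinates are given. Total counts ranged from 8.71 M to 41.6 M per library, with a median of 19.5 M. No pair of libraries, within a group or across groups, agreed within sampling noise, so all were counted as separate samples.

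Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, in 1 fit over all 69 libraries and 7 groups. Library sizes were scaled by TMM, and filterByExpr kept 15134 genes. The biological coefficient of variation was 0.35. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from this test unless another tool is named. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are given as CPM, counts scaled to a common library size, computed from the deposited counts with TMM scaling, as mean ± SD over replicates. The alternatives were median-ratio size factors in edgeR, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma 3.58.1 on the deposited variance-stabilized values, fits of the compared groups alone, each series of replicate sets alone, the series as a covariate, and the replicate number as a block. Refits without each library, without the 2 libraries absent from the variance-stabilized table and without 3 libraries that stood apart were chosen after seeing the data. The groups, the lists and the other alternatives were chosen before the data were examined.

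In all, 29 gene lists with 369 symbols were written before the data were examined; 1 symbol had no match and 3 matched by an older name. The 26 lists with at least 3 tested genes were tested with camera of limma at a preset correlation of 0.01 between genes, against all other tested genes, and again with an estimated correlation. A list was called at an adjusted p under 0.05 over the 26 lists. List counts give members that passed over all genes and members that passed when adjusted over the list alone. The estimated correlation kept the calls of the cholesterol synthesis, fatty acid synthesis and sterol sensing lists in 8 comparisons of the treatments, except the sterol sensing list in 25-HC addback against 48 h FBS; other kept calls are named beside their lists.

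The text names genes by a fixed rule. For each comparison it allowed the 8 largest rises and 8 largest falls among changed genes with a mean of at least 5 CPM, a regular symbol and the same sign in both series of replicate sets. It also allowed up to 4 changed members of each list, other members as values, and INSIG1, SQLE, SREBF2, ABCA1, ABCG1 and MYLIP in every comparison. Among these, genes whose calls held without each single library were preferred, a choice made after the values were seen. Some genes that the rule allowed, and 1 pattern that rested on such a gene, are not reported here. INSIG1 and ABCG1 did not pass the filter on low counts and were not tested.

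The descriptions number replicates 1 to 5 and 6 to 10 as 2 separate series of sets, which were treated as a possible batch. Whether replicate numbers pair the libraries was checked by correlating deviations from the group means. Over all groups the mean correlation was 0.40 for libraries of the same number and -0.04 for those of different numbers. Among different numbers it was 0.16 within the same series and -0.2 between the series. Deviations within a group sum to 0, so the negative means follow largely from this centring and are no observed baseline. Each pair correlated above 0.1 between 24 h LPDS+statin and 24 h FBS and between either addback and 48 h LPDS+statin. The same held between the 2 addbacks and between 48 h and 24 h FBS. The numbers were taken to pair the libraries in these comparisons, where pairs correlated at means of 0.40 to 0.52. Elsewhere these means were 0.34 to 0.46, and a few pairs fell below the bound. The bound of 0.1 lies below the 0.16 for other numbers of the same series. Passing it therefore does not separate pairing from a shared series. The pairing comes from the data and the shared numbers; no label names a shared culture day.

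The edgeR fit was tested on simulated data for the 24 h comparison of LPDS+statin with FBS, over 15134 genes with known changes. It recovered 14 of 50 genes changed 1.5-fold, 33 of 50 at 2-fold and 49 of 50 at 4-fold, with 6 false calls among 104. The raised simulated list passed camera and 2 unchanged ones did not. The simulated libraries were drawn independently, without series or shared replicate numbers, so these results need not hold for the real ones. With the replicate block the simulation gave 101 calls against 104, while the real comparison went from 127 to 412. Other software was Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

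Explanations weighed in the closing section were tested against written bounds. HSPA5, HAMP and IL21R entered the search for outlying libraries after their values had been seen.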

Results

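Gene expression was measured in HepG2 cells, a human hepatoma line, kept with serum lipoproteins, depleted of sterols, or given sterol back after depletion. The 69 libraries fell into 7 groups of 10 replicates, except 9 for serum with statin. Control cells were in 10% fetal bovine serum (FBS) for 24 h or 48 h. Depletion combined lipoprotein-deficient serum with 2 µM simvastatin for 24 h or 48 h (LPDS+statin). Another group had simvastatin in full serum for 24 h (FBS+statin). In the addback groups, LDL-cholesterol (LDL-C, 50 µg/ml) or the oxysterol 25-hydroxycholesterol (25-HC, 1 µg/ml) was present for the last 24 h after 24 h of depletion. Total counts had medians of 17.9 M to 21.54 M per group, with the lowest library at 8.71 M and the highest at 41.6 M. Replicates 1 to 5 and 6 to 10 formed 2 series of sets, and the series accounted for 39.4% of the first principal component, which held 20.4% of the variance. The median correlation with its own group lay below the fence of 0.937 for 48 h FBS replicate 5 (0.894), 25-HC replicate 10 (0.918) and FBS+statin replicate 8 (0.927).

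The first question was how these cells responded to 24 h of sterol depletion. Genes of cholesterol synthesis, fatty acid synthesis and LDL uptake rose together in LPDS+statin against 24 h FBS. HMGCS1, an early enzyme of cholesterol synthesis, went from 135 ± 65.4 to 641 ± 202 CPM (SD, n = 10 each) and lay above the FBS median in 10 of 10 libraries. Of the 20 enzymes of the cholesterol pathway, 19 rose, and the same number passed when adjusted over the list alone. HMGCS1 rose 4.76-fold (log2 2.25, SE 0.29, adjusted p = 7.62e-08), LSS 4.05-fold (log2 2.02, SE 0.23, adjusted p = 1.45e-09) and SQLE 2.67-fold (log2 1.41, SE 0.19, adjusted p = 1.62e-07). The exception was PMVK, with a log2 change of 0.08 (SE 0.28). The list's median log2 change was 1.53 (camera adjusted p = 1.24e-96), with 1.43 in replicates 1 to 5 and 1.67 in 6 to 10. In the fatty acid synthesis list, 7 of 17 genes rose, and 13 passed when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 3.69e-36; 0.73 and 0.87 in the 2 series). ACSS2, which makes acetyl-CoA from acetate, rose 5.90-fold, LPIN1 3.25-fold, the elongase ELOVL6 3.12-fold and ACLY, which makes cytosolic acetyl-CoA, 2.73-fold. In the sterol sensing and LDL uptake list, 6 of 14 genes rose (7 when adjusted over the list alone; median 0.41, camera adjusted p = 3.81e-16; 0.49 and 0.46 in the 2 series). Among them were TMEM97 and the sterol carrier STARD4 at 2.99-fold each and the regulator SREBF2 at 1.67-fold (adjusted p = 0.0178). SREBF2 lost its call without any 1 of 24 h FBS replicates 8 and 10 or LPDS+statin replicate 9 (highest adjusted p = 0.0823).

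Outside these lists, IL21R, a cytokine receptor gene, rose 8.73-fold at 24 h (log2 3.13, SE 0.54, adjusted p = 5.39e-05), from 2.29 ± 1.27 to 20.1 ± 8.62 CPM. An annotated antisense gene, IL21R-AS1, overlaps it and held 39 counts in all libraries. The strand setting of the counting is not known, so their reads may not be separated. The endothelial lipase gene LIPG rose 5.03-fold, the receptor gene P2RY8 4.92-fold and the transporter gene SLCO4C1 3.82-fold, and TTR, of the hepatocyte secreted list, rose 2.27-fold. HAMP, which encodes the iron-regulating hormone hepcidin, fell 4.65-fold, from 20.7 ± 10.9 to 4.46 ± 3.76 CPM (adjusted p = 0.00346). FLVCR2 fell 1.52-fold and PSMD2 1.34-fold. Among targets of the oxysterol receptor LXR, 1 of 12 fell, MYLIP, at 1.91-fold (adjusted p = 0.00355), while the cholesterol exporter gene ABCA1 had a log2 change of -0.01 (SE 0.15, adjusted p = 0.999). The Krüppel-like factor list had a median of 0.39 (camera adjusted p = 0.0147) with 0 of 4 genes called by edgeR over all genes or over the list alone. Its adjusted p was 0.0298 with an estimated correlation, 0.0554 with that and the replicate block, and 0.036 in replicates 1 to 5 and 0.0534 in 6 to 10 alone. The cell cycle list had a median of -0.37 (camera adjusted p = 1.86e-07), with an adjusted p of 0.463 with an estimated correlation. The immediate early list (median 0.41, camera adjusted p = 0.00673) had an adjusted p of 0.572 with an estimated correlation. The cholesterol storage list (median 0.21, camera adjusted p = 0.0246) had an adjusted p of 0.202 with an estimated correlation. The hepatocyte secreted list (median 0.18, camera adjusted p = 0.03) had an adjusted p of 0.572 with an estimated correlation. With the replicate block, 2 more lists passed camera: glucocorticoid targets (adjusted p = 0.032, against 0.304) and YAP/SRF targets (adjusted p = 0.0171, against 0.0553), but with an estimated correlation as well they did not (adjusted p = 0.0554 and 0.492).

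In all, 127 of 15134 tested genes changed at 24 h, 122 higher and 5 lower. Within replicates 1 to 5 the count was 89, of which 78 were shared with the 127, and within replicates 6 to 10 it was 67, of which 63 were shared. With the replicate number as a block, 412 genes passed, 324 higher and 88 lower, 127 of them shared.

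**Figure D1:**
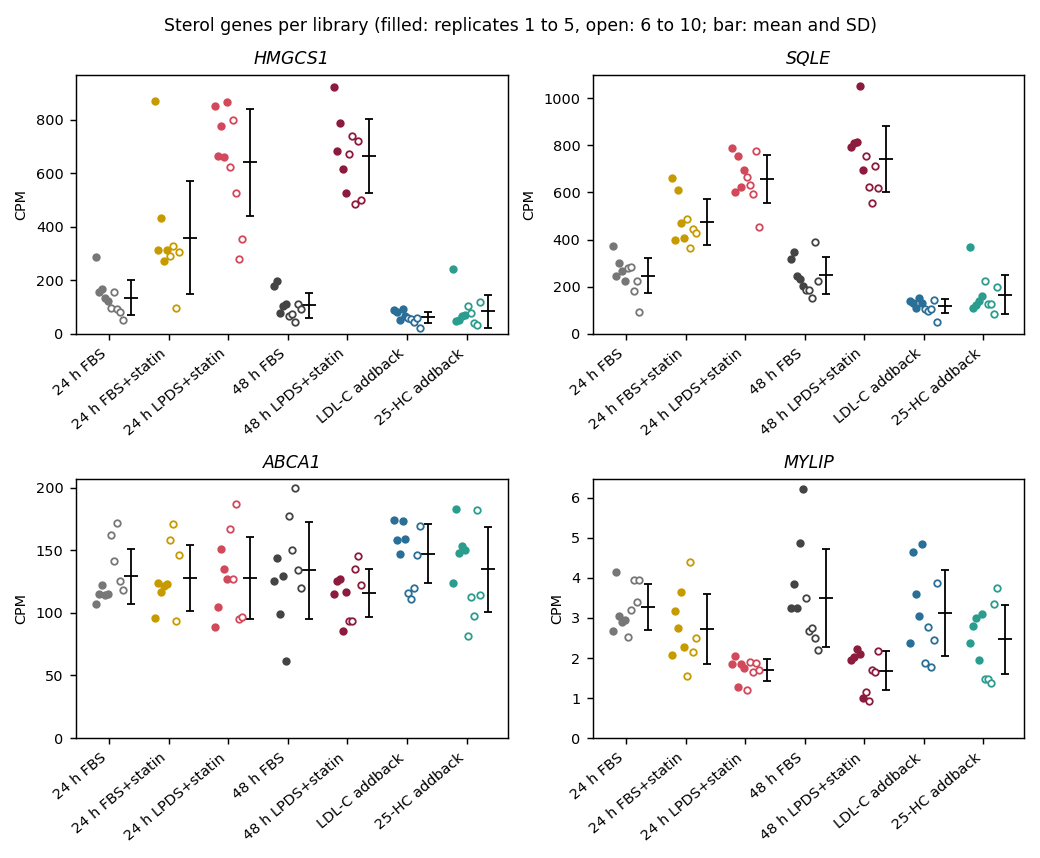
CPM of HMGCS1, SQLE, ABCA1 and MYLIP by group. Points are libraries, filled for replicates 1 to 5 and open for 6 to 10, and bars show the group means with their SD; HMGCS1 averaged 135 CPM in 24 h FBS, 641 in 24 h LPDS+statin, 666 in 48 h LPDS+statin and 62 after LDL-C addback.

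At 48 h, LPDS+statin was compared with 48 h FBS in the same way. The cholesterol synthesis enzymes again stood out, with 19 of 20 higher over all genes and 19 when adjusted over the list alone (median log2 1.65, camera adjusted p = 3.41e-63; 1.62 in replicates 1 to 5 and 1.55 in 6 to 10). HMGCS1 rose 6.27-fold (log2 2.65, SE 0.30, adjusted p = 6.93e-10) and MVD 5.47-fold (log2 2.45, SE 0.27, adjusted p = 5.16e-10). Of 17 fatty acid synthesis genes, 12 rose (13 higher and 1 lower when adjusted over the list alone; median 0.91, camera adjusted p = 3.65e-24; 0.86 and 0.87 in the 2 series). Among them were ACSS2 at 5.26-fold, the desaturase FADS2 at 4.59-fold, ELOVL6 at 3.66-fold and ACLY at 2.93-fold. In the sterol sensing list, 6 of 14 genes rose (7 when adjusted over the list alone; median 0.32, camera adjusted p = 2.09e-07; 0.29 and 0.57 in the 2 series). TMEM97 rose 3.49-fold and STARD4 3.32-fold. SREBF2 rose 1.60-fold (adjusted p = 0.0267), a call lost without any 1 of 48 h LPDS+statin replicates 4 and 6 or 48 h FBS replicates 5 and 10 (highest adjusted p = 0.0893). SQLE rose 2.99-fold. IL21R reached 42.1 ± 18.3 against 4.15 ± 2.9 CPM, a 10.1-fold rise (adjusted p = 1.43e-05), LIPG rose 6.40-fold and P2RY8 5.08-fold.

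Of the LXR targets, 3 of 12 fell at 48 h, over all genes and when adjusted over the list alone: MYLIP 2.05-fold, the sterol transporter gene ABCG8 1.66-fold and NR1H3, which encodes LXR alpha, 1.34-fold. The list's median was -0.06 (camera adjusted p = 0.0126), with an adjusted p of 0.337 with an estimated correlation. ABCA1 had a log2 change of -0.21 (SE 0.15, adjusted p = 0.615). The NR1H3 call was lost without any 1 of 10 libraries: 48 h LPDS+statin replicates 2, 3, 5, 6 and 7, 48 h FBS replicates 4, 5 and 8, 24 h FBS replicate 10 and 24 h LPDS+statin replicate 10 (highest adjusted p = 0.076). In the Krüppel-like factor list, KLF6 rose 1.82-fold and KLF10 rose as well (log2 0.59), 2 of 4 both over all genes and when adjusted over the list alone (median 0.48, camera adjusted p = 0.00477, adjusted p = 0.0112 with an estimated correlation). Camera called that list in neither series alone (medians 0.55 and 0.52, adjusted p = 0.0724 and 0.0888). KLF10 lost its call without any 1 of 48 h FBS replicates 2, 3 and 5 or 48 h LPDS+statin replicates 3, 6 and 7 (highest adjusted p = 0.0749). ATF3, a stress-induced factor, rose 2.29-fold, and TFRC, the transferrin receptor gene, rose 1.67-fold. Among genes that fell were ALDH6A1, of valine catabolism, at 1.83-fold, the sialyltransferase gene ST3GAL1 at 1.69-fold and PARS2 at 1.66-fold. Calreticulin (CALR) fell 1.73-fold, with a log2 change of -1.07 in replicates 1 to 5 and -0.32 in 6 to 10. HSPA5, the main chaperone of the endoplasmic reticulum (ER), was 1.87-fold lower over all replicates (adjusted p = 0.0389). Its log2 change was -1.49 in replicates 1 to 5 and 0.54 in 6 to 10, and its call was lost without any 1 of 13 libraries: 48 h FBS replicates 1, 3, 4 and 5, 48 h LPDS+statin replicates 2, 4, 5, 6, 8, 9 and 10, 24 h FBS replicate 10 and 24 h LPDS+statin replicate 10 (highest adjusted p = 0.175).

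The remaining list calls at 48 h did not hold with an estimated correlation. The immediate early list had a median of 0.64 (camera adjusted p = 9.51e-05; adjusted p = 0.355 with an estimated correlation). The ribosomal protein list had a median of -0.16 (camera adjusted p = 0.00378; adjusted p = 0.531 with an estimated correlation). The cell cycle list had a median of -0.25 (camera adjusted p = 0.0126; adjusted p = 0.724 with an estimated correlation), with 0.01 in replicates 1 to 5 and -0.44 in 6 to 10. The iron and heme list had a median of -0.23 (camera adjusted p = 0.0356; adjusted p = 0.391 with an estimated correlation). The prenylated GTPase list had a median of 0.10 (camera adjusted p = 0.0356; adjusted p = 0.531 with an estimated correlation). In all, 273 genes changed at 48 h, 201 higher and 72 lower, and 137 in a fit of the 2 groups alone, 125 higher and 12 lower. Replicates 1 to 5 gave 708 changed genes, 182 of them shared, and replicates 6 to 10 gave 213, 91 of them shared. For 547 genes the change differed between the 2 series in edgeR's test of that difference.

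**Figure D2:**
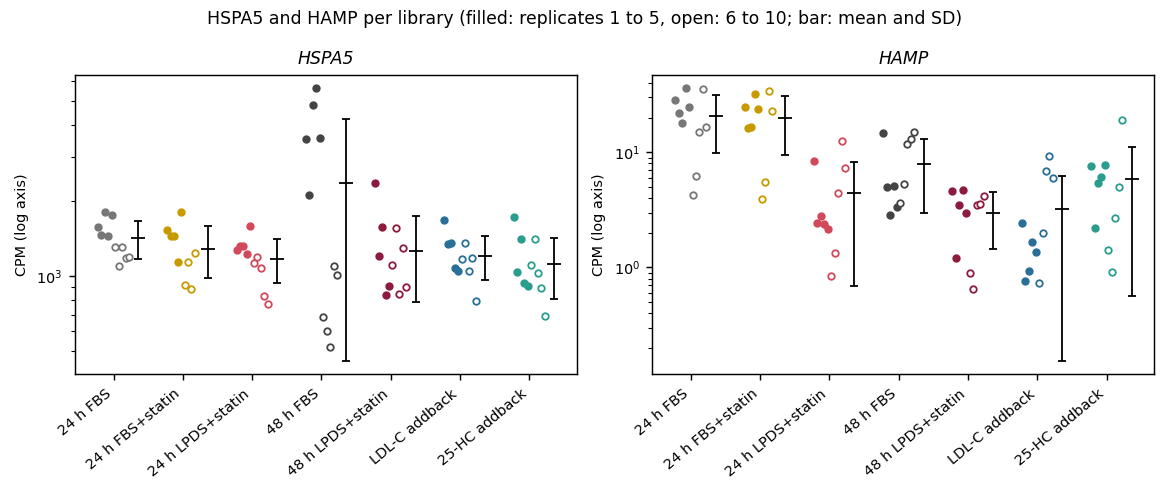
CPM, on a log axis, of HSPA5 and HAMP by group. Points are libraries, filled for replicates 1 to 5 and open for 6 to 10, and bars show means with SD; in 48 h FBS, HSPA5 averaged 3940 CPM in replicates 1 to 5 and 783 in 6 to 10.

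The 24 h and 48 h responses to LPDS+statin, which share no libraries, had 96 higher genes in common, where independent lists of 122 and 201 genes would share 1.62, and 2 lower genes in common, against 0.0238. No gene's response differed between the 2 times in edgeR's interaction test (0 genes; 570 at an unadjusted p under 0.05), while DESeq2 called 1 gene and limma on the variance-stabilized values 0. Without 48 h LPDS+statin replicate 2, edgeR called 1. The difference between the times was 0.17 for SQLE (SE 0.26), -0.06 for SREBF2 (SE 0.25), -0.20 for ABCA1 (SE 0.21) and -0.10 for MYLIP (SE 0.29), on the log2 scale, with an adjusted p of 0.999 for each.

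Simvastatin in full serum for 24 h, against 24 h FBS, tested the statin without lipoprotein removal. It raised cholesterol synthesis genes by less than 3-fold. ACSS2 rose 2.59-fold (log2 1.37, SE 0.21, adjusted p = 0.000233), from 73.5 ± 26.7 to 190 ± 77.6 CPM (n = 10 and 9), and SLCO4C1 2.22-fold (adjusted p = 0.00272). Both calls held without each library in turn. HMGCS1 rose 2.66-fold (adjusted p = 0.0208), LSS 2.23-fold (adjusted p = 0.016) and SQLE 1.92-fold (adjusted p = 0.0208). Each of these 3 lost its call without any 1 of FBS+statin replicate 3 or 24 h FBS replicates 8 and 10, and HMGCS1 and SQLE also without FBS+statin replicate 1 or 24 h FBS replicates 5 or 9 (highest adjusted p = 0.181 for HMGCS1, 0.0716 for LSS and 0.0817 for SQLE). In the cholesterol synthesis list 6 of 20 genes passed over all genes and 19 when adjusted over the list alone, with a median log2 change of 0.92 (camera adjusted p = 1.01e-63; 0.84 in replicates 1 to 5 and 0.91 in 6 to 10). For fatty acid synthesis it was 3 of 17, 8 when adjusted over the list alone (median 0.52, camera adjusted p = 4.41e-24; 0.47 and 0.44 in the 2 series). For sterol sensing it was 1 of 14, TMEM97, and 4 when adjusted over the list alone (median 0.16, camera adjusted p = 5.48e-07; 0.23 in each series). TMEM97 rose 1.84-fold, a call lost without any 1 of FBS+statin replicates 1, 3 and 4 or 24 h FBS replicates 2, 4, 5, 8, 9 and 10 (highest adjusted p = 0.214). SREBF2 had a log2 change of 0.44 (SE 0.18), MYLIP of -0.26 (SE 0.21) and ABCA1 of -0.02 (SE 0.15), with an adjusted p of 1.0 for each. Camera also called the hypoxia list (median -0.12, camera adjusted p = 0.000953; adjusted p = 0.294 with an estimated correlation) and the YAP/SRF list (median -0.06, camera adjusted p = 0.000953; adjusted p = 0.202 with an estimated correlation). The inflammation list (median -0.30, camera adjusted p = 0.00651) had an adjusted p of 0.202 with an estimated correlation, and the hepatocyte secreted list (median 0.12, camera adjusted p = 0.0433) one of 0.613 with an estimated correlation.

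In all, 13 genes rose with statin in serum and 0 fell by edgeR, with 378 at an unadjusted p under 0.05 in either direction. DESeq2 called 21 and limma on the variance-stabilized values 15. There were 3 such genes in a fit of the 2 groups alone and 3 in replicates 1 to 5, and replicates 6 to 10 gave 0 by edgeR, with 526 at an unadjusted p under 0.05. Leaving out FBS+statin replicates 1, 2, 3, 4 or 6 gave 3, 8, 2, 5 and 8 genes, and leaving out 24 h FBS replicates 2, 5, 8, 9 or 10 gave 5, 3, 2, 3 and 2. All 13 genes were also higher in 24 h LPDS+statin, where independent lists would share 0.105. Both comparisons used the same 24 h FBS libraries. With these split between them, FBS+statin gave 0 genes by edgeR (150 higher and 130 lower at an unadjusted p under 0.05 with even-numbered controls, 144 and 93 with odd-numbered), so how far the shared controls add to the 13 is open. Over all 15134 genes the 2 sets of log2 fold changes correlated at 0.49 with a covariance of 0.0351. In 100 simulations with shared controls and no effect these were 0.48 (0.46 to 0.51) and 0.0343 (0.0316 to 0.036). The simulated libraries were drawn independently, without series or shared replicate numbers. Real libraries of the same number in these groups correlated at means of 0.42 to 0.52. The simulations therefore cannot show whether the 2 responses agree beyond the shared controls. With the controls split between them, the correlation across genes was 0.15 or 0.20. Genes are not independent replicates.

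Between LPDS+statin and FBS+statin at 24 h, which differ in the serum, ACSS2 was 2.27-fold higher in LPDS+statin (log2 1.19, SE 0.22, adjusted p = 0.00494), LPIN1 2.09-fold (log2 1.06, SE 0.17, adjusted p = 0.000476), ACLY 1.71-fold (adjusted p = 0.0116) and the heparan sulfate proteoglycan gene SDC4 1.63-fold (adjusted p = 0.00497). The aldo-keto reductase gene AKR1C2 was 1.79-fold lower (adjusted p = 0.00497), below the FBS+statin median in 10 of 10 libraries. HAMP was 4.48-fold lower, 4.46 ± 3.76 against 20 ± 10.5 CPM (adjusted p = 0.0341), a call lost without any 1 of FBS+statin replicates 1, 4, 5, 8 and 9 or LPDS+statin replicates 2 to 8 (highest adjusted p = 0.121). None of the 20 cholesterol synthesis genes passed over all genes, and 16 were higher when adjusted over the list alone (median 0.65, camera adjusted p = 2.71e-27; 0.61 in replicates 1 to 5 and 0.84 in 6 to 10). For fatty acid synthesis 3 of 17 passed, 6 when adjusted over the list alone (median 0.44, camera adjusted p = 1.02e-10; 0.36 and 0.51 in the 2 series). The sterol sensing list had 0 of 14 called by edgeR over all genes and 5 when adjusted over the list alone (median 0.31, camera adjusted p = 8.18e-07; 0.28 and 0.35 in the 2 series). The YAP/SRF list had 0 of 16 and 4 (median 0.36, camera adjusted p = 1.97e-07, adjusted p = 0.0129 with an estimated correlation), and the Krüppel-like factor list 0 of 4 and 2 (median 0.43, camera adjusted p = 0.000475, adjusted p = 0.00248 with an estimated correlation). SQLE had a log2 difference of 0.47 (SE 0.19), SREBF2 0.29 (SE 0.19), MYLIP -0.67 (SE 0.21) and ABCA1 0.00 (SE 0.15). The cell cycle list had a median of -0.33 (camera adjusted p = 7.28e-06; adjusted p = 0.416 with an estimated correlation) and the immediate early list one of 0.54 (camera adjusted p = 5.14e-05; adjusted p = 0.293 with an estimated correlation). The inflammation list had a median of 0.75 (camera adjusted p = 0.00363; adjusted p = 0.139 with an estimated correlation), although HAMP, a member, fell, and the hypoxia list one of 0.21 (camera adjusted p = 0.00363; adjusted p = 0.379 with an estimated correlation). In all, 16 genes differed, 12 higher and 4 lower, and 31 in a fit of the 2 groups alone. Within replicates 1 to 5 there were 10, and replicates 6 to 10 gave 0 by edgeR, with 489 at an unadjusted p under 0.05. The count was 7 without FBS+statin replicate 5, 10 without replicate 8 and 7 without replicate 9. It was 10 without 24 h LPDS+statin replicate 6 and 25 without 25-HC replicate 10, and 9 without the 2 libraries absent from the variance-stabilized table.

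LDL-cholesterol given to depleted cells was compared with continued depletion at 48 h. It lowered the genes that depletion had raised: 19 of 20 cholesterol synthesis genes fell, over all genes and when adjusted over the list alone (median log2 -2.64, camera adjusted p = 4.85e-132; -2.58 in replicates 1 to 5 and -2.6 in 6 to 10). MVD fell 12.5-fold (log2 -3.64, SE 0.29, adjusted p = 1.63e-16), HMGCS1 10.7-fold (log2 -3.42, SE 0.31, adjusted p = 5.16e-14) and SQLE 6.36-fold (log2 -2.67, SE 0.20, adjusted p = 3.24e-17), each below the depleted median in 10 of 10 libraries. Of the fatty acid synthesis genes 13 of 17 fell, 14 when adjusted over the list alone (median -1.51, camera adjusted p = 7.73e-51; -1.53 and -1.42 in the 2 series). ACSS2 fell 7.59-fold, FADS2 7.51-fold, ACLY 4.18-fold and the desaturase SCD 3.92-fold. Of the sterol sensing genes 7 of 14 fell, over all genes and over the list alone (median -0.44, camera adjusted p = 5.14e-21; -0.72 and -0.45 in the 2 series). STARD4 fell 5.96-fold, the sterol importer gene NPC1L1 4.51-fold and SREBF2 2.75-fold. IL21R fell 23.6-fold, to 1.83 ± 1.82 CPM, P2RY8 10.1-fold and LIPG 9.76-fold.

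Smaller groups also moved with LDL-C. Of 16 YAP/SRF targets, 2 fell, the cytoskeletal genes TAGLN (2.34-fold) and VCL (1.51-fold), and 4 when adjusted over the list alone (median -0.40, camera adjusted p = 3.91e-07, adjusted p = 0.0152 with an estimated correlation; -0.69 and -0.16 in the 2 series). Of 10 immediate early genes, 2 fell, JUNB 2.42-fold and NR4A1 2.03-fold, and 7 when adjusted over the list alone (median -1.01, camera adjusted p = 9.98e-10; -1.42 and -0.77 in the 2 series). That list had an adjusted p of 0.0418 with an estimated correlation, and 0.066 with that and the replicate block. JUNB lost its call without LDL-C replicate 2 or 48 h LPDS+statin replicate 6 (highest adjusted p = 0.0651), and NR4A1 without LDL-C replicate 2 or 48 h LPDS+statin replicates 4 or 5 (highest adjusted p = 0.0659). The inflammation list had 2 of 8 genes lower, one of them the chemokine gene CXCL8 at 5.01-fold (0.241 against 1.22 CPM), and 3 when adjusted over the list alone (median -0.76, camera adjusted p = 2.2e-05, adjusted p = 0.0152 with an estimated correlation; -1.27 and -0.39 in the 2 series). The Krüppel-like factor list had 1 of 4 lower and 2 over the list alone (median -0.51, camera adjusted p = 0.00436, adjusted p = 0.0147 with an estimated correlation; adjusted p = 0.0104 in replicates 1 to 5 and 0.0946 in 6 to 10 alone). The stress response list had 2 of 16 lower, TRIB3 2.75-fold and ATF3 2.43-fold, and 3 when adjusted over the list alone (median -0.57, camera adjusted p = 1.3e-06; adjusted p = 0.175 with an estimated correlation). The cell cycle list had a median of 0.53 (camera adjusted p = 6.51e-07; adjusted p = 0.366 with an estimated correlation), 0.89 in replicates 1 to 5 and -0.03 in 6 to 10, and the hypoxia list one of -0.23 (camera adjusted p = 0.0199; adjusted p = 0.432 with an estimated correlation). With the replicate block the bile acid and drug metabolism list also passed camera (adjusted p = 0.0225, against 0.0526; adjusted p = 0.172 with an estimated correlation as well). MYLIP rose 1.84-fold, the lysosomal protease gene CTSB 1.73-fold, the transporter gene SLC16A10 1.79-fold, CLMN 1.80-fold and ZMAT3, a p53 target, 1.57-fold. ABCA1 had a log2 change of 0.35 (SE 0.15, adjusted p = 0.321). In all, 315 genes changed, 46 higher and 269 lower. Replicates 1 to 5 gave 827, 273 of them shared, and replicates 6 to 10 gave 99, 94 of them shared. The replicate block gave 897, 315 of them shared, with 332 higher and 565 lower.

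The oxysterol 25-HC, given at 1 µg/ml in place of LDL-C, also lowered the same pathways against 48 h LPDS+statin. Again 19 of 20 cholesterol synthesis genes fell, over all genes and when adjusted over the list alone (median log2 -2.32, camera adjusted p = 7.81e-138; -2.26 in replicates 1 to 5 and -2.33 in 6 to 10). LSS fell 9.56-fold (log2 -3.26, SE 0.24, adjusted p = 2.01e-17), HMGCS1 7.84-fold (log2 -2.97, SE 0.30, adjusted p = 7.4e-12) and SQLE 4.49-fold (log2 -2.17, SE 0.19, adjusted p = 6.7e-14). Of the fatty acid synthesis genes 11 of 17 fell, among them FADS2 9.46-fold, ACSS2 9.38-fold, ACLY 4.65-fold and SCD 3.71-fold. When adjusted over the list alone 12 fell and 1 rose (median -1.36, camera adjusted p = 9.58e-50; -1.43 and -1.06 in the 2 series). Of the sterol sensing genes 7 of 14 fell, also over the list alone (median -0.38, camera adjusted p = 8.57e-22; -0.62 and -0.54 in the 2 series). STARD4 fell 4.15-fold, TMEM97 3.60-fold and SREBF2 2.09-fold. Of the YAP/SRF targets 3 of 16 fell and 8 when adjusted over the list alone (median -0.51, camera adjusted p = 7.59e-13, adjusted p = 0.000587 with an estimated correlation; -0.73 and -0.47 in the 2 series). TAGLN fell 3.71-fold, VCL 1.66-fold and TPM1 1.38-fold. TPM1 lost its call without 48 h LPDS+statin replicate 1 (adjusted p = 0.0561). The cell cycle list had a median of 0.51 (camera adjusted p = 7.33e-08; adjusted p = 0.431 with an estimated correlation). IL21R fell 11.5-fold and P2RY8 8.15-fold. Genes that rose included CTSB (1.86-fold), the noncoding HNF4A-AS1 (1.94-fold; it lies antisense to HNF4A, and the strand setting is not known), ALDH6A1 (1.57-fold), the cation channel gene TRPV1 (1.58-fold) and FLVCR2 (1.49-fold). Of the LXR targets, ABCA1 had a log2 change of 0.21 (SE 0.15, adjusted p = 0.86) and MYLIP 0.54 (SE 0.20, adjusted p = 0.31). In all, 238 genes changed, 16 higher and 222 lower. Replicates 1 to 5 gave 344, 202 of them shared, and replicates 6 to 10 gave 85, 80 of them shared. The replicate block gave 532, 238 of them shared, with 96 higher and 436 lower.

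**Figure D3:**
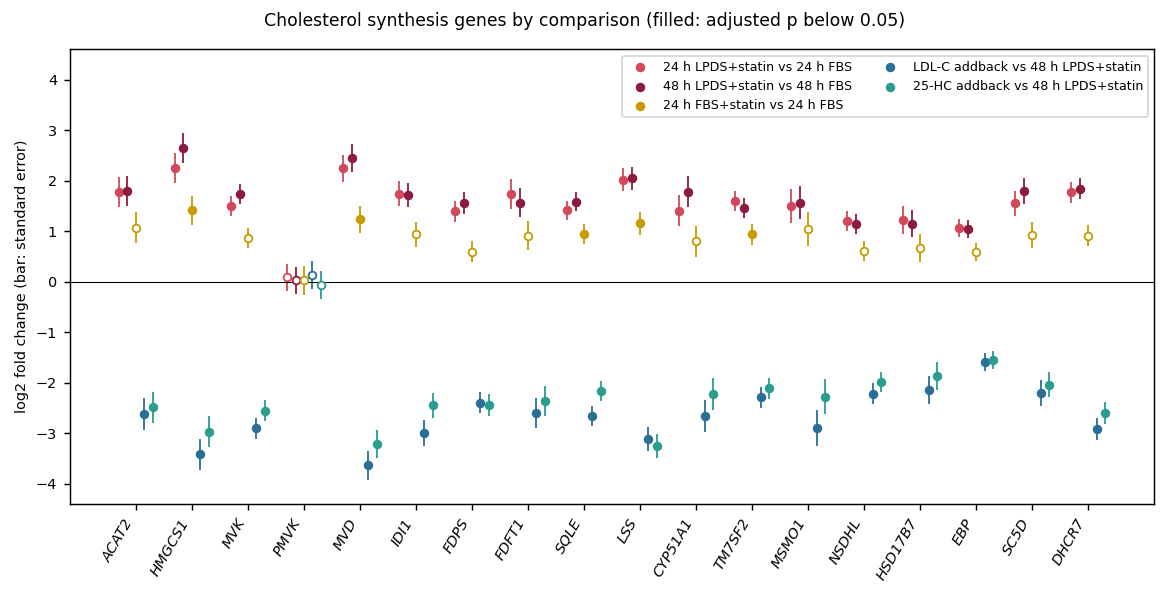
Log2 fold changes of 18 of the 20 cholesterol synthesis genes, with standard errors as bars, in the depletion, statin and addback comparisons, filled where the adjusted p was below 0.05. HMGCS1 lies at 2.25 and 2.65 in LPDS+statin at 24 h and 48 h, 1.41 in FBS+statin, and -3.42 and -2.97 after LDL-C and 25-HC, while PMVK was at 0.08 at 24 h.

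To ask how far addback moved depletion's genes back, genes changed by 48 h LPDS+statin were chosen in odd-numbered replicates and measured in even-numbered ones. Each choice used a fit of 48 h FBS, 48 h LPDS+statin and the addback group in question, so the chosen genes differ between the addbacks. All 45 such genes moved in the opposite direction with LDL-C (100%, 95% exact Clopper-Pearson interval 92.1 to 100, which covers counting error over genes only), and 31 of 31 did with 25-HC (interval 88.8 to 100). Over all genes the share was 51.7% and 61.5%. All of these genes were ones that depletion had raised, and their median ratio of the addback change to the depletion change was -1.42 for LDL-C and -1.13 for 25-HC. With genes chosen in even-numbered replicates and measured in odd-numbered ones it was -1.24 over 36 genes and -1.27 over 26. The addbacks shared 168 lower genes, where independent lists of 269 and 222 would share 3.95, and 8 higher genes, against 0.0486. Both used the same 48 h LPDS+statin libraries. With those libraries split between the comparisons, 79 lower genes were shared, against 1.22. In that split 25-HC raised 0 genes by edgeR (95 at an unadjusted p under 0.05), so the overlap of higher genes is open.

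Between the addbacks, which differ in compound and in dose (50 against 1 µg/ml), few differences passed. The log2 difference, 25-HC minus LDL-C, was 0.50 for SQLE (SE 0.19), 0.40 for SREBF2 (SE 0.18), -0.13 for ABCA1 (SE 0.15) and -0.34 for MYLIP (SE 0.20). None of these passed in the main fit, which does not pair the libraries. By replicate number, MYLIP was lower with 25-HC in each pair except replicate 9 (3.35 against 2.46 CPM). Of 2 genes that passed, the plexin gene PLXNC1 was 1.78-fold lower with 25-HC, 15.4 ± 3.86 against 27.6 ± 7.79 CPM (adjusted p = 0.015), and below the LDL-C median in 10 of 10 libraries. It lost its call without any 1 of LDL-C replicates 2, 4, 6 and 7 or 25-HC replicates 3, 6, 7 and 8 (highest adjusted p = 0.128). The nuclear receptor gene NR4A3, chosen after its values were seen, had a log2 difference of 3.26 (adjusted p = 0.015) at a mean of 0.377 CPM over all libraries. DESeq2 called 6 genes, limma on the variance-stabilized values 1, the replicate block 32 and a fit of the 2 groups alone 0 by edgeR, with 612 at an unadjusted p under 0.05. Replicates 1 to 5 gave 2, neither of them shared, and replicates 6 to 10 gave 0 by edgeR, with 1100 at an unadjusted p under 0.05. The count was 9 without the 3 libraries that stood apart, 5 without 25-HC replicate 10, 1 without 25-HC replicates 6 or 7, LDL-C replicate 6 or 48 h LPDS+statin replicates 3, 4 or 8, and 0 by edgeR without 25-HC replicates 3 or 8 or LDL-C replicates 4 or 7. Camera called 6 lists, all higher with 25-HC, with 0 members passing edgeR over all genes. Replicates 1 to 5 alone kept 5 of these calls, without metallothioneins. Replicates 6 to 10 alone kept 2, immediate early and metallothioneins. The immediate early list had 7 of 10 genes higher when adjusted over the list alone (median 1.02, camera adjusted p = 6.45e-10; adjusted p = 0.195 with an estimated correlation). The hypoxia list had a median of 0.34 (camera adjusted p = 2.37e-05; adjusted p = 0.195 with an estimated correlation). The stress response list had a median of 0.20 (camera adjusted p = 9.9e-05; adjusted p = 0.464 with an estimated correlation) with 5 genes adjusted over the list alone. The cholesterol synthesis list had a median of 0.26 (camera adjusted p = 0.00103; adjusted p = 0.464 with an estimated correlation) with 0 by edgeR adjusted over the list alone. The metallothionein list had a median of 0.26 (camera adjusted p = 0.00186; adjusted p = 0.464 with an estimated correlation), and the inflammation list one of 0.72 (camera adjusted p = 0.00222; adjusted p = 0.195 with an estimated correlation) with 2 adjusted over the list alone. With the replicate block, glucocorticoid targets (adjusted p = 0.0464, against 0.134) and YAP/SRF targets (adjusted p = 0.0398, against 0.0834) also passed camera, but not with an estimated correlation as well (adjusted p = 0.116 and 0.476).

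Against 48 h FBS, cells given LDL-C after depletion had lower cholesterol synthesis genes than cells never depleted. In that list 10 of 20 genes were lower, and 18 when adjusted over the list alone (median log2 -0.94, camera adjusted p = 3.27e-31; -1.0 in replicates 1 to 5 and -0.95 in 6 to 10). IDI1 was 2.43-fold lower (log2 -1.28, SE 0.24, adjusted p = 0.00192), MVK 2.25-fold (log2 -1.17, SE 0.20, adjusted p = 0.000932) and SQLE 2.12-fold (log2 -1.09, SE 0.19, adjusted p = 0.000932). NPC1L1, of the sterol sensing list, was 2.57-fold lower (log2 -1.36, SE 0.18, adjusted p = 2.09e-06). ABCA1 had a log2 difference of 0.14 (SE 0.15) and MYLIP -0.15 (SE 0.20). In replicates 1 to 5 ABCA1 ran from 147 to 174 CPM after LDL-C against 61.6 to 144 CPM in 48 h FBS. In 6 to 10 it ran from 111 to 169 against 120 to 200 CPM, so the series leaned in opposite directions. SREBF2 was 1.72-fold lower (adjusted p = 0.0229), a call lost without LDL-C replicate 2 (adjusted p = 0.0695). The fatty acid synthesis list had 2 of 17 lower, SCD (1.94-fold) and the lipase gene PNPLA3 (1.83-fold), and 6 when adjusted over the list alone (median -0.48, camera adjusted p = 2.67e-09; -0.56 and -0.39 in the 2 series). The sterol sensing list had 2 of 14 lower and 5 over the list alone (median -0.18, camera adjusted p = 1.64e-06; -0.33 and -0.16 in the 2 series, and not called in replicates 6 to 10 alone, adjusted p = 0.109). TFRC was 2.00-fold higher and the zinc transporter gene SLC39A10 2.02-fold (log2 changes 0.14 and 1.76 in the 2 series). The other lists camera called did not hold with an estimated correlation: stress response (median -0.36, camera adjusted p = 4.77e-06; adjusted p = 0.237 with an estimated correlation; -1.38 and 0.35 in the 2 series), YAP/SRF targets (median -0.22; adjusted p = 0.237 with an estimated correlation) and metallothioneins (median -0.59; adjusted p = 0.324 with an estimated correlation). The same held for p53 targets (median 0.32; adjusted p = 0.161 with an estimated correlation), inflammation (median -0.60; adjusted p = 0.237 with an estimated correlation), ribosomal proteins (median -0.12; adjusted p = 0.65 with an estimated correlation), iron and heme (median -0.27; adjusted p = 0.324 with an estimated correlation) and cell cycle (median 0.27; adjusted p = 0.732 with an estimated correlation). In all, 68 genes differed, 17 higher and 51 lower, and 20 in a fit of the 2 groups alone, 1 higher and 19 lower. DESeq2 called 173, replicates 1 to 5 gave 555 and replicates 6 to 10 gave 20. For 372 genes the change differed between the series. The count was 132 without 48 h FBS replicate 1, 41 without replicate 8, 105 without replicate 10, 38 without LDL-C replicate 2 and 31 without LDL-C replicate 6.

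After 25-HC, 4 of 20 cholesterol synthesis genes were below 48 h FBS, and 14 when adjusted over the list alone (median log2 -0.70, camera adjusted p = 1.14e-20; -0.66 in each series). LSS was 2.31-fold lower (log2 -1.21, SE 0.22, adjusted p = 0.00294), CALR 2.04-fold (log2 changes -1.32 and -0.55 in the 2 series) and the disulfide isomerase gene PDIA4 1.87-fold (-1.16 and -0.39). TFRC was 2.08-fold higher (adjusted p = 0.000625) and the noncoding SNHG12 1.83-fold. SQLE had a log2 difference of -0.58 (SE 0.19, adjusted p = 0.205), SREBF2 -0.39 (SE 0.18, adjusted p = 0.485), ABCA1 0.00 (SE 0.15) and MYLIP -0.49 (SE 0.20). In replicates 1 to 5 ABCA1 ran from 124 to 183 CPM after 25-HC against 61.6 to 144 CPM in 48 h FBS. In 6 to 10 it ran from 81.8 to 182 against 120 to 200 CPM. The 0.00 thus averages series that leaned in opposite directions. The fatty acid synthesis list had 4 of 17 lower and 6 adjusted over the list alone (median -0.34, camera adjusted p = 3.11e-06; -0.44 and -0.19 in the 2 series), and the YAP/SRF list 1 of 16 in both counts, TAGLN, at 2.56-fold (median -0.35, camera adjusted p = 2.66e-06, adjusted p = 0.0409 with an estimated correlation; -0.46 and -0.23 in the 2 series). TAGLN lost its call without 48 h FBS replicate 5 (adjusted p = 0.0671). The sterol sensing list had 0 of 14 by edgeR and 2 adjusted over the list alone (median -0.17, camera adjusted p = 9.4e-05; adjusted p = 0.059 with an estimated correlation; -0.20 and -0.07 in the 2 series). In replicates 6 to 10 alone camera did not call the fatty acid synthesis (adjusted p = 0.202), YAP/SRF (0.0531) and sterol sensing (0.236) lists. The immediate early list (median 0.71; adjusted p = 0.594 with an estimated correlation; 0.02 and 1.31 in the 2 series), p53 targets (median 0.34; adjusted p = 0.35 with an estimated correlation), the interferon list (median -0.29; adjusted p = 0.35 with an estimated correlation) and the cell cycle list (median 0.24; adjusted p = 0.79 with an estimated correlation) passed only at the preset correlation. In all, 51 genes differed, 10 higher and 41 lower, and 2 in a fit of the 2 groups alone, 1 higher and 1 lower. DESeq2 called 95, limma on the variance-stabilized values 23, replicates 1 to 5 gave 185 and replicates 6 to 10 gave 70. For 327 genes the change differed between the series. The count was 23, 28, 16, 19, 12 and 24 without 25-HC replicates 3, 5, 6, 7, 8 and 9 in turn. It was 15 without 48 h FBS replicate 5, 24 without replicate 8, 30 without 24 h FBS replicate 10, 26 without 24 h LPDS+statin replicate 10 and 14 without the 2 libraries absent from the variance-stabilized table.

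The time in culture alone was examined by comparing 48 h with 24 h FBS. All 20 cell cycle genes fell, over all genes and when adjusted over the list alone (median log2 -1.52, camera adjusted p = 5.48e-24; -1.67 in replicates 1 to 5 and -1.28 in 6 to 10), with an adjusted p of 0.0814 with an estimated correlation and 0.0209 with that and the replicate block. The ribonucleotide reductase gene RRM2 fell 3.92-fold (log2 -1.97, SE 0.34, adjusted p = 1.96e-05), cyclin A2 (CCNA2) 3.45-fold (log2 -1.79, SE 0.28, adjusted p = 3.77e-06) and MCM4, of the replicative helicase, 3.25-fold (log2 -1.70, SE 0.26, adjusted p = 2.07e-06). The replication genes MCM10 (4.02-fold) and CDC45 (3.70-fold) fell as well. Stress response genes rose, 12 of 16 over all genes and 14 when adjusted over the list alone (median 1.08, camera adjusted p = 1.36e-07; adjusted p = 0.21 with an estimated correlation). Asparagine synthetase (ASNS) rose 4.69-fold, the transcription factor DDIT3 4.10-fold, the cystine transporter SLC7A11 3.46-fold and TRIB3 2.87-fold. Bile acid and drug metabolism genes rose in 6 of 14 cases, 8 when adjusted over the list alone, with CYP8B1 and NR0B2 at 2.21-fold each (median 0.74, camera adjusted p = 0.000414). Its adjusted p was 0.21 with an estimated correlation and 0.0227 with that and the replicate block. Of 10 immediate early genes 5 rose and 8 when adjusted over the list alone, EGR1 4.16-fold among them (2.76-fold without 48 h FBS replicate 1; list median 0.91, camera adjusted p = 0.000997; adjusted p = 0.385 with an estimated correlation). FOS rose 8.41-fold, a call lost without 48 h FBS replicate 1 (2.41-fold, adjusted p = 0.141). Of 7 glucocorticoid targets 3 rose, TSC22D3 4.86-fold, TAT 3.37-fold and DUSP1 2.60-fold, and FKBP5 fell 1.81-fold. Adjusted over the list alone 5 rose and 1 fell (median 1.17, camera adjusted p = 0.0174). That list's adjusted p was 0.21 with an estimated correlation and 0.0154 with that and the replicate block.

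Plasma protein genes rose in 4 of 16 cases, 6 when adjusted over the list alone (median 0.29, camera adjusted p = 0.00251; adjusted p = 0.336 with an estimated correlation), with TTR at 2.56-fold and AHSG at 1.99-fold from 24 h to 48 h FBS. Sterol sensing genes rose in 5 of 14, 6 adjusted over the list alone (median 0.36, camera adjusted p = 0.00279), with the lysosomal exporter NPC1 at 1.80-fold and NPC1L1 at 1.52-fold. The adjusted p was 0.21 with an estimated correlation and 0.0364 with that and the replicate block. Cholesterol storage genes rose in 4 of 12, with PLIN5 at 3.91-fold, and 5 rose and 2 fell adjusted over the list alone (median 0.37, camera adjusted p = 0.0483; adjusted p = 0.293 with an estimated correlation). The ribosomal protein list, a sign of RNA quality and growth, had 2 of 20 higher in both counts (median 0.31, camera adjusted p = 0.000741; adjusted p = 0.385 with an estimated correlation). Cholesterol synthesis genes had a median of -0.02 (camera adjusted p = 0.754). SQLE had a log2 change of 0.01 (SE 0.19), ABCA1 0.05 (SE 0.15) and MYLIP 0.09 (SE 0.20). SREBF2 rose 1.45-fold (adjusted p = 0.027), a call lost without any 1 of 24 h FBS replicates 2, 8 and 10 or 48 h FBS replicates 6 and 9 (highest adjusted p = 0.0905). The complement receptor gene C5AR1 rose 14.1-fold and the activin gene INHBE 5.67-fold, and TXNIP, induced by glucose, fell 5.52-fold (9.19-fold without 48 h FBS replicate 10) and APOBEC3B 4.81-fold. Markers of other cell types that rose were PDGFRB (2.59-fold, at 52.1 ± 25.1 CPM), VWF (3.87-fold, at 1.26 ± 1.17 CPM) and CDH16 (2.00-fold, at 9.93 ± 5.9 CPM). In all, 2898 genes changed, 1445 higher and 1453 lower. Replicates 1 to 5 gave 2468, 1864 of them shared, and replicates 6 to 10 gave 1039, 933 of them shared. The replicate block gave 4946, 2888 of them shared.

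**Figure D4:**
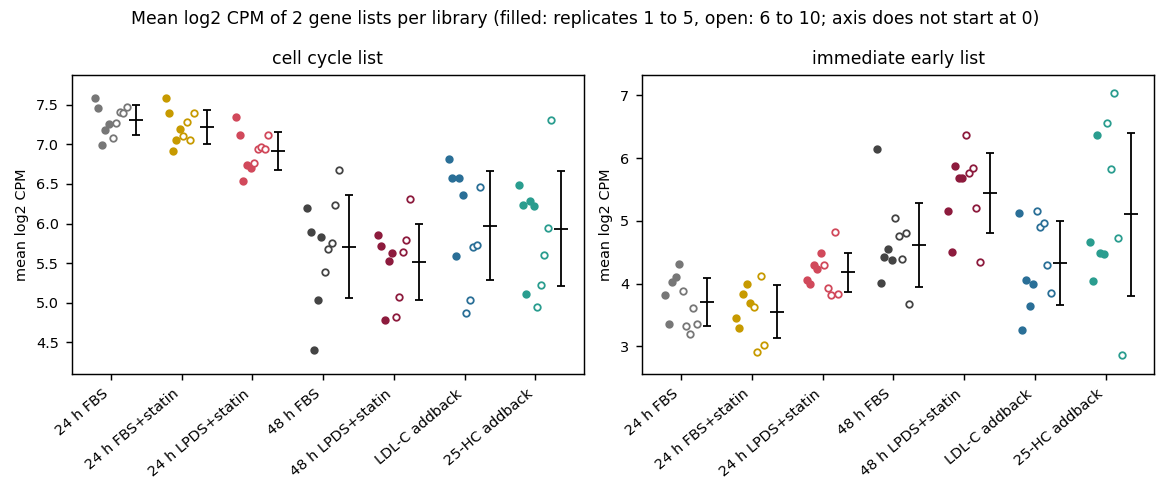
Mean log2 CPM of the cell cycle and immediate early lists by group, on axes that do not start at 0. Points are libraries and bars show means with SD; the cell cycle mean was 7.31 in 24 h FBS and 5.71 in 48 h FBS.

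Several lists were called in none of the 11 comparisons by camera. The isoprenoid branch and prenylation list had medians from -0.09 to 0.08 (lowest camera adjusted p = 0.344), the list of genes encoded by the mitochondrial genome, a sign of RNA quality, from -0.13 to 0.24 (lowest 0.510), and PPARA targets from -0.06 to 0.18 (lowest 0.176). In replicates 6 to 10 alone, the mitochondrial list was called in 48 h LPDS+statin, LDL-C and 25-HC against 48 h FBS, in FBS+statin against 24 h FBS and in the difference between the times, and in replicates 1 to 5 alone in that difference. Retinoid targets had medians from -0.25 to 0.29 (lowest camera adjusted p = 0.395), and markers of other epithelial lines from -0.18 to 0.22 (lowest 0.133; called in FBS+statin against 24 h FBS without the 2 libraries absent from the variance-stabilized table). Marker lists of blood, endothelial cells and fibroblasts had only 2 tested genes each and were not tested as lists. INSIG1, a sterol-regulated retention protein gene, held 188 counts and ABCG1, an LXR target, 19 counts in all 69 libraries, and both were left out of the tests for low counts. Whether the annotation or the counting lost reads of INSIG1 was not tested.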

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

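Of the tests in this part, those of 48 h FBS replicate 5, of the series in HSPA5 and its 3 companions, of the chaperones in replicates 6 to 10 and of the series in HAMP were chosen after the result was seen; those of the 10 further chaperones and of the BMP genes were written before.

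HSPA5 and 3 other ER chaperone genes were lower at 48 h in LPDS+statin than in FBS over all replicates. The change differed between the 2 series of sets in 4 of these 4 genes when adjusted over the 4 and in 2 when adjusted over all genes, and 10 further chaperones had a median difference of -1.18 on the log2 scale, replicates 1 to 5 minus 6 to 10. In 48 h FBS, HSPA5 averaged 3940 ± 1360 CPM in replicates 1 to 5 and 783 ± 257 in 6 to 10, against 1380 ± 620 and 1140 ± 292 in LPDS+statin (n = 5 each). The median log2 change of the 4 genes was -0.78 without 48 h FBS replicate 5, so that library alone does not account for it, and -0.19 in replicates 6 to 10, so neither does a fall of this size in every replicate. All 4 genes had higher means in 48 h FBS in replicates 1 to 5 than in 6 to 10. None of the 10 further chaperones was lower in LPDS+statin in replicates 6 to 10. Their log2 changes there ran from 0.04 (PDIA6) to 1.33 (HSPA13), and HSPA5 was at 0.54. In replicates 6 to 10 HSPA5 was lower in 48 h FBS than in LPDS+statin. High levels in the first series thus do not describe the whole difference. HSPA5 differed between the series more in 48 h FBS than in LPDS+statin. The change differed between series for 547, 372 and 327 genes in 48 h LPDS+statin, LDL-C and 25-HC against 48 h FBS. That count was 5 for 48 h against 24 h FBS and 0 or 1 in each comparison without 48 h FBS. The labels do not give the cause of the difference between the series.

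HAMP was lower in LPDS+statin than in FBS+statin at 24 h. The log2 change was -2.65 (SE 0.67) in replicates 1 to 5 and -1.65 (SE 0.68) in 6 to 10, so the fall was seen in both series. The difference between the series had an unadjusted p of 0.289 in edgeR. With so few libraries this cannot exclude that the size of the fall differs between them. With statin in full serum HAMP had a log2 change of -0.05 against FBS (SE 0.47); no group had lipoprotein-deficient serum without statin. Lower BMP-SMAD signalling, which drives HAMP, was tested on 8 genes with a median log2 change of -0.38, which did not decide it.

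A search for single libraries far from the rest of their group made 98 tests and found 15, where chance would give 4.9. In total counts, 24 h FBS replicate 4 held 28.16 M. In genes with a count, 48 h FBS replicate 5 had 12735 and 48 h LPDS+statin replicate 5 had 16356. In 25-HC replicate 1, SQLE was at 368 CPM and the cholesterol synthesis list had a mean of 6.82 log2 CPM, both above the other 9 libraries. SQLE was at 1050 CPM in 48 h LPDS+statin replicate 4. IL21R was at 18.6 CPM in FBS+statin replicate 3, HSPA5 at 2360 CPM in 48 h LPDS+statin replicate 1 and HAMP at 19.0 CPM in 25-HC replicate 10. The fatty acid synthesis mean was 6.14 in 24 h FBS replicate 10 and 7.18 in 24 h LPDS+statin replicate 10. The sterol sensing mean was 6.37 in 48 h FBS, 5.72 in LDL-C addback, 6.71 in 24 h LPDS+statin and 7.1 in 48 h LPDS+statin, each in replicate 10.

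The LPDS+statin response differed between 48 h and 24 h for 4 lists by camera on the interaction. Replicates 1 to 5 alone kept 0 of these calls, and replicates 6 to 10 alone kept 2, ribosomal proteins and prenylated GTPases. Metallothioneins had a median of -0.79 (camera adjusted p = 0.0102), ribosomal proteins -0.21 (0.0102), prenylated GTPases 0.19 (0.0137) and p53 targets 0.36 (0.0297), and with an estimated correlation the adjusted p was 0.745 for each. INSIG1, left out of the tests for low counts, was at 0.18 CPM in 24 h LPDS+statin (42 counts, in 6 of 10 libraries, 35 of them in replicates 1 to 5) and 0.494 CPM in 48 h LPDS+statin (110 counts, in 7 of 10 libraries, 98 of them in replicates 1 to 5), against 2 counts in 24 h FBS and 6 in 48 h FBS; this was a signal outside the main tests.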

How the results depend on the processing

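Of 291 values of named genes, the 262 that passed the test kept their direction in every alternative except HSPA5 in replicates 6 to 10. There its log2 change was 0.54 in 48 h LPDS+statin and 0.39 in 25-HC addback, both against 48 h FBS. Genes named as the largest rises or falls had been chosen to keep their sign in both series. For them the direction in either series alone was fixed in advance and is no support. DESeq2 left 291 of 291 within the bounds set beforehand, RLE size factors 290, the set series as a covariate 290, the variance-stabilized values 245, replicates 1 to 5 alone 205 of 290 and replicates 6 to 10 alone 118 of 290. For the moved counts below the cause was not tested. At this depth INSIG1 and ABCG1 were left out of the tests for low counts.

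With the replicate number as a block, counts of changed genes were 412 and 953 (568 higher and 385 lower) for LPDS+statin against FBS at 24 h and 48 h, 62 for FBS+statin, 350 for LPDS+statin against FBS+statin, 897 and 532 for LDL-C and 25-HC against 48 h LPDS+statin, 32 between the addbacks, 4946 for 48 h against 24 h FBS, 1 for the difference between the times, and 594 and 399 for LDL-C and 25-HC against 48 h FBS. Pairs did not all correlate above 0.1 in the comparisons with FBS+statin, nor in those with 48 h FBS other than the one with 24 h FBS. The numbers were not taken to pair the libraries there.

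In replicates 1 to 5 counts were 708 for LPDS+statin at 48 h, 3 for FBS+statin, 10 for LPDS+statin against FBS+statin, 827 for LDL-C, and 555 and 185 for LDL-C and 25-HC against 48 h FBS. In replicates 6 to 10 they were 67 for LPDS+statin at 24 h, 99 for LDL-C, 85 for 25-HC, 1039 for 48 h against 24 h FBS, 20 for LDL-C against 48 h FBS, and 0 by edgeR for FBS+statin (526 at an unadjusted p under 0.05), LPDS+statin against FBS+statin (489) and between the addbacks (1100). With the series as a covariate they were 424 for LPDS+statin at 48 h, 28 for FBS+statin, 32 for LPDS+statin against FBS+statin, 6 between the addbacks, 1 for the difference between the times, and 167 and 89 for LDL-C and 25-HC against 48 h FBS.

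In fits of the compared groups alone counts were 137 for LPDS+statin at 48 h (125 higher and 12 lower), 3 for FBS+statin, 31 for LPDS+statin against FBS+statin, 20 and 2 for LDL-C and 25-HC against 48 h FBS, and 0 by edgeR between the addbacks (612 at an unadjusted p under 0.05; DESeq2 6). DESeq2 gave 21 for FBS+statin, 44 for LPDS+statin against FBS+statin, 6 between the addbacks, 1 for the difference between the times, and 173 and 95 for LDL-C and 25-HC against 48 h FBS. The variance-stabilized values gave 1 between the addbacks and 23 for 25-HC against 48 h FBS. Without a filter there were 4 for FBS+statin, 1 between the addbacks and 18 for 25-HC against 48 h FBS, and with the stricter filter 1 between the addbacks. Without the 2 libraries absent from the variance-stabilized table there were 9 for LPDS+statin against FBS+statin and 14 for 25-HC against 48 h FBS, and without the 3 libraries apart 9 between the addbacks.

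Leaving out 1 library at a time gave 109 to 145 genes for LPDS+statin at 24 h, 219 to 327 at 48 h, 2 to 16 for FBS+statin, 7 to 25 for LPDS+statin against FBS+statin, 241 to 344 for LDL-C, 201 to 257 for 25-HC, 0 to 5 between the addbacks by edgeR, 2432 to 3245 for 48 h against 24 h FBS, 0 to 1 for the difference between the times, and 31 to 132 and 12 to 65 for LDL-C and 25-HC against 48 h FBS.

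With an estimated correlation, the number of lists called by camera went from 8 to 4 for LPDS+statin at 24 h, 10 to 4 at 48 h, 7 to 3 for FBS+statin, 9 to 5 for LPDS+statin against FBS+statin, 6 to 0 between the addbacks, 9 to 0 for 48 h against 24 h FBS, 4 to 0 for the difference between the times, and 11 to 3 and 8 to 3 for LDL-C and 25-HC against 48 h FBS. It was 4 for LPDS+statin at 48 h in replicates 1 to 5, and for 25-HC, with 5 lists, 9 in replicates 1 to 5 and 8 without the 3 libraries apart. The correlation of LPDS+statin and FBS+statin fold changes fell from 0.49 to 0.15 or 0.20 with the controls split.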

Other observations

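The test of random splits of the libraries was written before any result was seen. The swaps within pairs followed the check of whether replicate numbers pair the libraries.

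Across the groups, the mean log2 CPM of the cholesterol synthesis list rose with depletion and fell with addback. It was 6.32 ± 0.47 in 24 h FBS (SD), 7.19 ± 0.35 in FBS+statin and 7.87 ± 0.27 in 24 h LPDS+statin. At 48 h it was 6.3 ± 0.25 in FBS, 7.93 ± 0.19 in LPDS+statin, 5.46 ± 0.32 after LDL-C and 5.64 ± 0.5 after 25-HC. IL21R was also highest in 48 h LPDS+statin, at 42.1 ± 18.3 CPM, against 4.15 ± 2.9 CPM in 48 h FBS, and was at 1.83 ± 1.82 CPM after LDL-C and 3.66 ± 4.46 CPM after 25-HC, where replicates 1, 6 and 7 held 6.39, 12.5 and 10.3 CPM.

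Whether groupings unrelated to treatment could give these counts was tested by fitting the compared groups alone and dividing their libraries at random in 100 ways, the real one included. For 24 h LPDS+statin against 24 h FBS, the real grouping gave 185 genes, 4 of 100 gave as many and the highest other gave 2520. For 48 h LPDS+statin against 48 h FBS these were 137, 1 and 88. For FBS+statin against 24 h FBS they were 3, 1 and 1, and for LPDS+statin against FBS+statin 31, 1 and 0 by edgeR. For LDL-C addback against 48 h LPDS+statin they were 305, 1 and 4, and for 25-HC addback 181, 3 and 371. For 48 h against 24 h FBS they were 2472, 1 and 3. Against 48 h FBS they were 20, 1 and 1 for LDL-C and 2, 1 and 1 for 25-HC. For 25-HC against LDL-C the real grouping gave 0 genes by edgeR, 100 of 100 gave as many and the highest other gave 124, and for the difference between the 2 times these were 0, 100 and 114; with 0 genes in the real grouping every other gives as many, so these 2 tests decide nothing. Dividing the libraries of a comparison by series instead gave 2444 to 6154 genes. The grouping with 2520 genes had 2 of 10 libraries from replicates 1 to 5 in 1 of its groups, and the one with 371 had 7 of 10. The groupings with 88 and 124 genes had 8 and 7 of 10. All of these lean towards that division. The highest other groupings for 48 h against 24 h FBS and LDL-C against 48 h FBS leaned as well, at 8 and 7 of 10. They gave only 3 genes and 1 gene, so a lean did not always bring a high count. Whether the lean brought the high counts was not tested. Where the replicate numbers were taken to pair the libraries, swapping the members of pairs was tried as well, in 100 ways with the real one. In the 4 such comparisons with genes in the real grouping, the highest other count was 0 by edgeR for 24 h LPDS+statin against 24 h FBS and for 25-HC addback, 102 for LDL-C addback and 618 for 48 h against 24 h FBS, below the real count in each. The groupings with 102 and 618 genes differ from the real one by a single pair.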
